A study of Hordeum vulgare with 12 samples.

How the data were processed

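Leaf RNA of 12 barley samples was measured by sequencing: accessions BCS8 and BCS24, each in control and under drought, with 3 libraries per group. The label "ck" was read as control. Per the labels, RNA with a RIN above 7 was selected for poly(A) tails, made into dUTP-stranded libraries and read from both ends on an Illumina NovaSeq. The drought protocol, the age of the seedlings and the origin of the replicates are not given. Per the submitters' processing notes, StringTie 2.1.6, DESeq2 and edgeR were used, without a role for each. The aligner and the genome build are not given in the sources used here, and neither is how reads shared between like genes were counted, so coordinates are as the deposited table gives them.

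The deposited gene table gives, per the file headers, whole-number counts and FPKM for each library and 30157 genes, with a gene type, ontology terms, orthology numbers and, for some genes, a description. The authors deposited a second table with counts and FPKM for 143596 transcripts. No step that made the count or FPKM values is recorded beyond the names of the tools, and in the deposited tables counts over FPKM were 1 constant per gene times 1 factor per library. Every column matched a sample. Before the files were seen, a limma model of log2(FPKM + 1) had been planned because only FPKM was expected. As the table holds counts, counts were tested in their place, and the planned model became an alternative.

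Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, 17342 in all, 16085 of them typed as protein coding, 235 as rRNA and 96 as snoRNA. Counts were scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with all 12 libraries in 1 fit and 1 coefficient per group (8 residual degrees of freedom, prior degrees of freedom 2.47, common dispersion 0.091). The comparisons and the gene lists with their fallback terms were written before the data were examined. The count test replaced the planned limma model, and additions made later are named as such. The comparisons were drought against control in each accession, the difference between these effects (the interaction), and BCS24 against BCS8 in control and under drought. P-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. Errors of log2 fold changes are the fold change over the square root of the F value. A group with 0 counts was given a bound, from 3 counts in each library. Libraries held 49553836 to 61212440 counts, and in data simulated from these dispersions the same script recovered 33% of 2-fold changes in BCS8 and 38% in BCS24, 85% and 77% of 4-fold ones, with 1.7 to 8.4% of calls false. The simulation drew each gene independently, with no accession differences and no variation shared by the genes of a library. These shares need not hold for the real libraries.

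Gene lists had been set as words to be found in descriptions, with an ontology term for each as a fallback. Only 29.2% of tested genes have a description, so the fallback terms were used, for the 25 lists with at least 5 genes. No fallback had been set for NAC, WRKY, ERF, heat stress transcription factor and reference gene lists. The 21 lists by description were added as a second family after the data were seen, and in them a pattern that also matched the word methionine was corrected after its result was seen. Lists were tested with camera (limma 3.58.1) at a correlation of 0.01 between genes, again with an estimated correlation, under which no list passed, and adjusted over the lists of a family. Fry, a further limma test planned for the lists, passed 5 of the 25 lists in BCS8, 0 in BCS24 and 0 in the interaction. Between the accessions it passed 7 in control and 8 under drought. By description it passed 1 of 21 lists in BCS8, 2 in BCS24, 0 in the interaction, and 4 and 1 between the accessions. Counts of genes are given over all genes, and adjusted over the list alone. Ontology terms with 10 to 500 tested genes (1199 terms, background of 15339 genes with a term) were tested with a 1-sided Fisher test, for higher and lower genes apart. An ontology term says how a gene was annotated, not what it does in barley leaf.

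Genes named in the text are, for each comparison, the 8 largest rises and falls among genes past the threshold with a mean FPKM of at least 5 in the higher group, no overlap between the groups and a usable description, plus 2 members of each list. Of 3 against 3 libraries 10% of genes lack overlap by chance alone. The rule could choose from 34 genes in BCS8 and 89 in BCS24, and 453 and 707 between the accessions. Other genes are named as picked after their values were seen, as are members of ontology terms and of the interaction.

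Same-numbered libraries were checked for pairing through the correlation of their deviations from the group means. Only the drought libraries of the 2 accessions deviated together for every number (0.143, 0.267 and 0.185). The labels state no pairing, and libraries with different numbers were not compared, so these values do not show one. For accession under drought the count with this number as a block is given as an alternative, in a fit of the 6 drought libraries. A block over all 12 kept that count within 1.5 times. Within accessions the correlations ran from −0.407 to 0.241, and between controls from −0.145 to 0.216.

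Alternatives set before the files were seen were limma on log2(FPKM + 0.1) and on quantile-normalized values, no filter, median-of-ratios scaling, a replicate block, a 2-fold minimum, sums of transcript counts, a fit of only the 6 libraries compared, and each library left out. Limma on log2(FPKM + 1), first planned as the main test, became an alternative once the files were seen to hold counts. DESeq2 1.42.0, rRNA share as a covariate, removal of rRNA and organelle genes, and removal of BCS8 drought 3 with BCS24 control 1 were added after the data were seen. Groups of values per library were compared by exact permutation. A table pairing locus tags with symbols did not match the gene identifiers and was left out.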

Results

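The series held 12 leaf libraries of barley accessions BCS8 and BCS24, each grown as control or under drought, with 3 libraries per group. Accession separated the libraries first: component 1 took 56.9% of the variance, with BCS8 at −109 to −59.5 and BCS24 at 60.9 to 90.2. Component 2 took 13.7% and separated the drought libraries of BCS24 (−38.74 to −28.53) from its controls (3.18, 53.98 and 58.7), of which BCS24 control 1 lay closest to them. BCS8 drought 3 also lay apart, at −69.72 against 9.03 and 26.13 for the other drought libraries of BCS8. Pearson correlations of log2 values were 0.919 to 0.982 within groups and 0.782 to 0.967 between groups. Library totals ran from 49553836 to 61212440 counts.

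**Figure D1:**
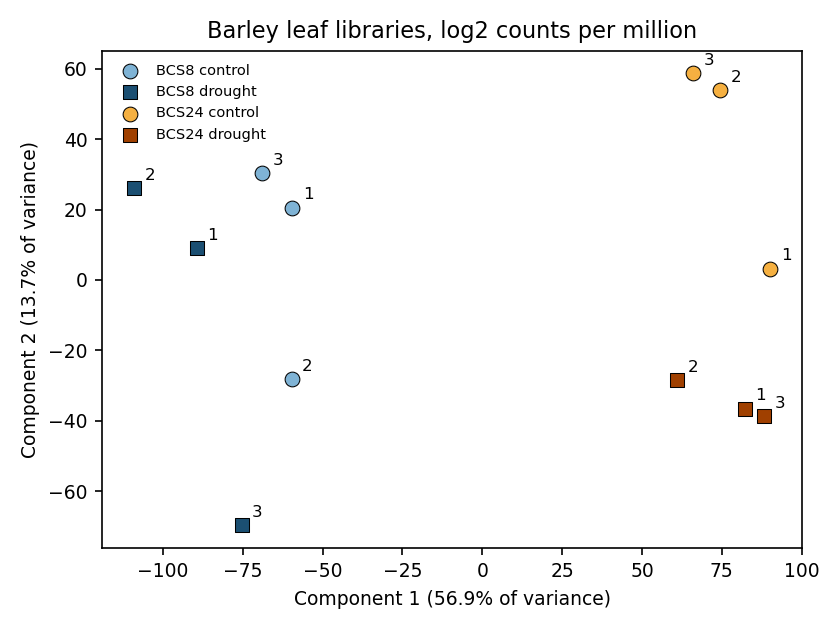
Each point is 1 barley library, placed by log2 CPM (scaled counts) on component 1 (56.9% of variance) and component 2 (13.7%), with the replicate number beside it and colour for the 4 groups. BCS8 lies on the left and BCS24 on the right, and BCS24 control 1 lies at 3.18 on component 2.

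The make-up of the libraries differed between control and drought in opposite directions in the 2 accessions by group mean. Only for the number of genes did control and drought lie apart without overlap in both accessions. Genes with at least 1 FPKM numbered 15812 ± 35.7 (mean ± SD) in BCS8 control and 16151 ± 172 in BCS8 drought, against 15977 ± 119 and 15508 ± 176 in BCS24. The share of counts in rRNA genes was 0.771 ± 0.239% and 1.65 ± 0.666% in BCS8 control and drought, and 1.35 ± 0.775% and 0.486 ± 0.248% in BCS24. The 10 most counted genes held 6.33 ± 0.497% and 5.43 ± 0.832% in BCS8, and 6.60 ± 0.547% and 8.12 ± 0.588% in BCS24. Within 1 accession no such measure can reach an exact permutation p under 0.1 with 3 against 3 libraries. These shares move with the same groups as the gene changes that follow, and with rRNA share as a covariate the drought counts of genes fell to 29 in BCS8 and 15 in BCS24. The count for the mean drought effect over both accessions did not fall with it (1299, against 1191 without the covariate). As rRNA share moved by 0.875 percentage points in BCS8 and −0.865 in BCS24, it nearly cancels in that mean. The unchanged count therefore does not test whether the mean effect depends on rRNA share.

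In BCS8, drought raised 4 of the 8 genes of abscisic acid (ABA) biosynthesis, all of the 9-cis-epoxycarotenoid dioxygenase type, an enzyme of the ABA pathway. HORVU5Hr1G008050 rose by a log2 fold change of 4.34 ± 0.49 (± SE, adjusted p = 0.0106, n = 3 per group, edgeR), and HORVU5Hr1G092850 rose from 2.27 to 32.0 counts scaled to a common total per library (CPM; 3.81 ± 0.76, edgeR adjusted p = 0.0433). HORVU5Hr1G054970 and HORVU5Hr1G044510 rose by 3.70 ± 0.76 and 3.48 ± 0.71, with values so close to those of HORVU5Hr1G092850 that shared reads cannot be ruled out. The other 4 members, with zeaxanthin epoxidase HORVU2Hr1G078840 among them (−0.24), did not pass. HORVU5Hr1G092850 and HORVU5Hr1G054970 were each not past the threshold in 9 of 18 alternatives. The ABA receptor gene HORVU4Hr1G055220 fell from 6.35 to 0.949 CPM (−2.74 ± 0.49). A delta-1-pyrroline-5-carboxylate synthase gene of proline synthesis, HORVU3Hr1G085760, rose by 1.94 ± 0.36 (edgeR adjusted p = 0.0311).

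Other rises in BCS8 were those of a RING-type E3 ubiquitin transferase, HORVU5Hr1G059280 (5.29 ± 1.09, 0.982 to 38.3 CPM), and of EDTS5, HORVU4Hr1G071300 (3.76 ± 0.57, 7.45 to 100.8). A homeobox-leucine zipper gene, HOX22-like HORVU2Hr1G092710, rose by 2.79 ± 0.52, and a glycosyltransferase, HORVU1Hr1G007810, by 2.66 ± 0.36. Phenylalanine ammonia-lyase HORVU6Hr1G058820 (2.24 ± 0.47), ferredoxin HORVU5Hr1G117910 (1.98 ± 0.41) and trehalose 6-phosphate phosphatase HORVU1Hr1G053770 (1.77 ± 0.31) rose too. Among the falls, carboxypeptidase HORVU4Hr1G016730 fell by 1.41 ± 0.24, glycosyltransferase HORVU7Hr1G097550 by 1.38 ± 0.25, Cyclin-U1-1 HORVU2Hr1G107830 by 1.31 ± 0.22, and a DETOXIFICATION transporter, HORVU2Hr1G068090, by 1.20 ± 0.25. ACR12 HORVU5Hr1G042310 (−1.06 ± 0.19), HvSnRK1gamma HORVU2Hr1G069060 (−0.99 ± 0.19), carboxypeptidase HORVU2Hr1G023450 (−0.93 ± 0.17) and purple acid phosphatase HORVU5Hr1G020400 (−0.93 ± 0.18) also fell.

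Of the 199 genes annotated to water deprivation in BCS8, 14 rose and 4 fell over all genes, and 25 and 9 when adjusted over the list alone. Of 189 genes of ABA signalling, 10 rose and 1 fell (22 and 4 adjusted over the list alone). The protein phosphatase 2C genes HORVU3Hr1G059170 (2.44 ± 0.41) and HORVU3Hr1G085930 (1.72), picked after their values were seen, were among them, and a like gene outside the list, HORVU4Hr1G060370, rose by 3.60 ± 0.46. Of the 121 genes of the heat response 3 rose, with HORVU3Hr1G020390 (2.66 ± 0.44) among them, and 1 fell. Of 445 defence genes 7 rose and 4 fell, beside 173 and 93 of all 17342 tested genes. The allene oxide synthase gene HORVU5Hr1G098090, of the jasmonate pathway, rose by 1.51 ± 0.21, while none of the 8 genes annotated to jasmonic acid metabolism passed in edgeR. Peroxidases HORVU3Hr1G077580 (2.26 ± 0.41) and HORVU1Hr1G016660 (1.74 ± 0.36) and heat stress transcription factor A2c HORVU1Hr1G083420 (1.19 ± 0.23) rose, the glutathione transferase gene HORVU5Hr1G085070 fell (−0.82 ± 0.13), and glutathione transferase HORVU2Hr1G124300 rose on 12 counts in control and 51 in drought (2.13 ± 0.37). This last call is weak, at 0.19 and not past the threshold in limma on log2(FPKM + 1). The call was not past it in 11 of 18 alternatives.

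By camera, the ABA biosynthesis list rose in BCS8 (adjusted p = 3.31e-06; adjusted p = 0.278 with an estimated correlation). So did the 135 genes of the cytosolic large ribosomal subunit (median 0.16, 112 positive, adjusted p = 0.0266; adjusted p = 0.878 with an estimated correlation). The ribosomal list held no gene past the threshold. Among lists drawn from gene descriptions, added after the data were seen, 5 rose by camera. Proline and glycine betaine had 5 of 5 genes positive (adjusted p = 0.000945; 0.256 with an estimated correlation), and heat stress transcription factors 8 of 8 (adjusted p = 0.00111; 0.0817). The others were photosystems (58 of 84 positive, adjusted p = 0.0227; 0.948), jasmonate (13 genes, adjusted p = 0.0429; 0.948) and cytosolic ribosomal proteins (35 genes, adjusted p = 0.0394; 0.948). Ontology terms past the threshold numbered 10 among the risen genes and 0 among the fallen ones by Fisher's test. Water deprivation (14 genes, 2.04 expected, adjusted p = 1.99e-05), negative regulation of ABA signalling (7 of 40, 0.41 expected, adjusted p = 5.87e-05), peptidyl-threonine phosphorylation (5 of 14, 0.14 expected) and ethylene signalling (6 of 81, adjusted p = 0.0308) were among the 10.

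In total 266 of 17342 genes passed in BCS8 (edgeR, adjusted p < 0.05), 173 higher and 93 lower, of which 140 and 50 changed at least 2-fold. The share of higher genes was 65% here, 54.9% with limma on log2(FPKM + 0.1) and 51.2% after quantile normalization. Leaving out BCS8 control 1 left 0 genes, control 3 left 33 and drought 1 left 84. Only 2 genes passed with just the 6 BCS8 libraries in the fit, 29 with the rRNA covariate, and 1182 with DESeq2. In simulated data of this layout 33% of 2-fold changes and 85% of 4-fold changes were recovered, so a gene below the threshold is not shown to be unchanged.

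In BCS24, drought raised genes of starch breakdown and of ABA synthesis, and single genes of methionine and S-adenosylmethionine metabolism, which no fixed list tests as a group. HvMS, the methionine synthase gene HORVU5Hr1G006780, rose from 1671 to 5420 CPM (1.70 ± 0.24, edgeR adjusted p = 0.0126, n = 3 per group). Adenosylhomocysteinase HORVU2Hr1G110120 rose by 1.73 ± 0.24, S-adenosylmethionine synthase HORVU6Hr1G063490 by 1.61 ± 0.24 and serine hydroxymethyltransferase HORVU2Hr1G110110 by 1.60 ± 0.23, and in BCS8 HvMS (0.15) and adenosylhomocysteinase (0.52) did not pass. Genes of starch breakdown rose: alpha-1,4 glucan phosphorylases HORVU3Hr1G085380 (1.59 ± 0.21, edgeR adjusted p = 0.00997) and HORVU3Hr1G085420 (1.58 ± 0.24), and, picked after their values were seen, DPE2 HORVU2Hr1G021700 (0.97 ± 0.13), isoamylase 3 HORVU5Hr1G070160 (1.13 ± 0.20) and phosphoglucan water dikinase HORVU7Hr1G008070 (0.57 ± 0.12). Beta-amylase HORVU3Hr1G032160 rose by 0.72 ± 0.13 and phospholipase D HORVU5Hr1G084740 by 1.60 ± 0.31. The same 4 dioxygenase genes of ABA biosynthesis rose as in BCS8, with HORVU5Hr1G092850 at 3.78 ± 0.78 (0.836 to 11.5 CPM) and HORVU5Hr1G008050 at 2.21 ± 0.47. These calls are not firm in BCS24. HORVU5Hr1G092850 was not past the threshold in 11 of 18 alternatives and HORVU5Hr1G054970 in 12 of 18.

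Falls in BCS24 included HvSnRK1gamma HORVU2Hr1G069060, from 67.4 to 23.5 CPM (−1.52 ± 0.20, edgeR adjusted p = 0.00897), and the ABA receptor gene HORVU4Hr1G055220, from 21.2 to 2.54 (−3.06 ± 0.49). AT-hook gene HORVU4Hr1G060280 fell by 1.93 ± 0.27, root phototropism protein 2 HORVU4Hr1G023260 by 1.75 ± 0.34 and an adenine nucleotide alpha hydrolase-like gene, HORVU6Hr1G068990, by 1.54 ± 0.24. Cyclin-U1-1 HORVU2Hr1G107830 fell by 1.51 ± 0.22, APT5 HORVU2Hr1G087090 by 1.45 ± 0.31 and glucose-6-phosphate 1-epimerase HORVU2Hr1G101360 by 1.27 ± 0.20. The ACC oxidase gene HORVU6Hr1G079640, of the ethylene pathway, fell by 1.89 ± 0.34, the 12-oxophytodienoate reductase gene HORVU2Hr1G004230 by 3.50 ± 0.63, and NAC genes HORVU4Hr1G051360 and HORVU7Hr1G055080 by 1.26 ± 0.29 and 1.12 ± 0.24. The 2 NAC genes were not past the threshold in 11 and 9 of 18 alternatives. The small-subunit rRNA locus ENSRNA049489482 fell by 6.67 ± 1.48, beside a fall of rRNA share in the same libraries. Its counts in BCS24 control were 9, 987 and 94. Heat stress transcription factor A-2 HORVU5Hr1G094380 (1.05 ± 0.18), annexin HORVU7Hr1G037080 (1.44 ± 0.31), cellulose synthase HORVU5Hr1G110000 (1.0 ± 0.19) and beta-tubulin HORVU3Hr1G078940 (0.81 ± 0.16) rose. So did the chlorophyll a-b binding genes HORVU5Hr1G087250 and HORVU5Hr1G124160 (both 1.09), whose near-equal values leave shared reads open. They were not past the threshold in 10 and 11 of 18 alternatives.

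The lists of the Calvin cycle and of chlorophyll synthesis rose in BCS24 with 0 single genes past the threshold over all genes. Of 10 splits of the BCS24 samples 3 passed as many lists by ontology, the real one included, so the lists below are not told from chance. By fry 0 of the 25 lists by ontology passed in BCS24. The 84 photosystem genes by description did not rise as a list (40 positive, median −0.18, camera adjusted p = 0.639). All 8 Calvin cycle genes were positive (median 0.55, 0 past over all genes, 6 higher adjusted over the list alone, camera adjusted p = 0.0033; adjusted p = 0.509 with an estimated correlation). Of 26 genes of chlorophyll synthesis 24 were positive (median 0.45, 0 past over all genes, 8 adjusted over the list alone, camera adjusted p = 0.00013; 0.418 with an estimated correlation). The other lists that rose were ABA biosynthesis (4 of 8 genes, adjusted p = 0.000544; 0.418 with an estimated correlation) and antioxidant enzymes (1 of 7, 3 adjusted over the list alone, adjusted p = 0.0163; 0.509). The cytosolic large ribosomal subunit (106 of 135 positive, adjusted p = 0.0057; 0.701) rose as well. So did water deprivation (12 higher and 1 lower of 199, 28 and 7 adjusted over the list alone, adjusted p = 0.0285; 0.418). The median of the water deprivation list was 0.10, and −0.02 with limma on log2(FPKM + 1). Trehalose biosynthesis by ontology (1 of 18 lower, median −0.32, HORVU3Hr1G071570 at −0.83 ± 0.14, adjusted p = 0.0285; 0.418) and glutathione transferases (1 higher and 1 lower of 62, adjusted p = 0.0329; 0.418) fell as lists. The 7 raffinose and trehalose genes by description did not pass (camera adjusted p = 0.639), with a median of 0.07 in edgeR and −0.06 with limma on log2(FPKM + 1).

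By description, 7 of 21 lists rose in BCS24 by camera, and 2 of the 21 passed by fry. Chlorophyll synthesis had 13 of 13 genes positive (adjusted p = 0.000695; 0.444 with an estimated correlation), and the Calvin cycle 12 of 12 (adjusted p = 0.00279; 0.573). Reference genes, a control list that drought should leave in place, had 20 of 22 positive (median 0.30, adjusted p = 0.00148, and 0.444 with an estimated correlation). As this control list passed too, a pass by camera in BCS24 does not by itself mark a list as responding to drought. The others were sucrose, fructan and starch (22 genes, adjusted p = 0.00279; 0.444), plastid ribosomal proteins (30 genes, 9 higher adjusted over the list alone, adjusted p = 0.00279; 0.444), jasmonate (13 genes, adjusted p = 0.00752; 0.444) and cytosolic ribosomal proteins (adjusted p = 0.0353; 0.794). LEA and dehydrin genes by description, 9 in all, had 0 past the threshold by edgeR in either accession (2 higher in BCS8, 2 higher and 2 lower in BCS24 adjusted over the list alone). By Fisher's test 14 ontology terms passed among the risen genes of BCS24 and 0 among the fallen. Chloroplast stroma (27 of 458, 6.9 expected, adjusted p = 1.68e-06), thylakoid (11 of 130, adjusted p = 0.00258), starch catabolic process (4 of 16, adjusted p = 0.0134), fatty acid biosynthesis (7 of 72, adjusted p = 0.0137) and sterol biosynthesis (4 of 19, adjusted p = 0.0177) were among the 14.

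BCS24 had 460 genes past the threshold (edgeR), 243 higher and 217 lower, with 146 and 124 changed at least 2-fold. Higher genes made up 52.8%, but 26.2% of 751 with limma on log2(FPKM + 0.1) and 23% of 766 on log2(FPKM + 1), where the median of all genes lay at −0.13 and −0.10. Leaving out BCS24 control 2 left 27 genes, control 3 left 19, drought 1 left 38 and drought 2 left 67.

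**Figure D2:**
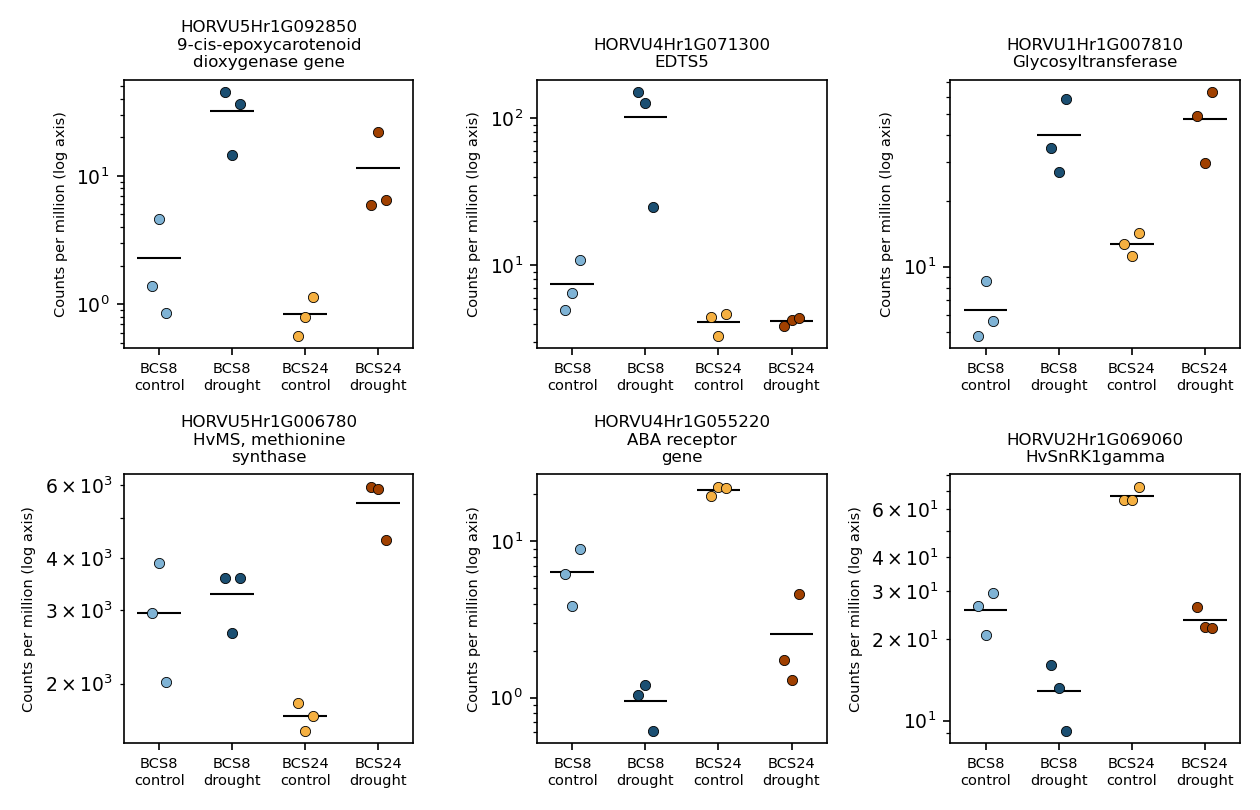
CPM on a log axis for 6 genes in the 4 groups, with 1 point per library and a bar at the group mean. HORVU5Hr1G092850 rises in both accessions (2.27 to 32.0 in BCS8), HORVU4Hr1G071300 passed the threshold in BCS8 alone (7.45 to 100.8), and HORVU2Hr1G069060 falls in both (67.4 to 23.5 in BCS24).

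Genes that changed the same way in both accessions numbered 40 higher (2.42 expected, Fisher p = 1.66e-37) and 28 lower (1.16 expected, Fisher p = 2.03e-31), and 1 changed in opposite directions. These p-values are a description only, since genes are not independent and both comparisons share 1 estimate of the spread per gene. The 4 dioxygenase genes of ABA biosynthesis, RING-type E3 HORVU5Hr1G059280 (5.29 in BCS8, 6.65 ± 1.36 in BCS24 on 7 counts in control and 724 in drought), glycosyltransferase HORVU1Hr1G007810 (2.66 and 1.90), phosphatase 2C HORVU4Hr1G060370 (3.60 and 3.27 ± 0.45) and a gene annotated as kinase and ubiquitin ligase, HORVU7Hr1G076440 (1.51 ± 0.31 and 2.25 ± 0.32), were among the 40. ABA receptor HORVU4Hr1G055220, HvSnRK1gamma HORVU2Hr1G069060, trehalose-phosphate synthase HORVU3Hr1G071570 (−0.68 ± 0.14 and −0.83 ± 0.14), 12-oxophytodienoate reductase HORVU2Hr1G004230 (−2.95 ± 0.62 and −3.50 ± 0.63) and Cyclin-U1-1 HORVU2Hr1G107830 were among the 28. The auxin response factor gene HORVU7Hr1G033820 rose in both (1.55 ± 0.17 and 0.85 ± 0.17). Of the genes called in BCS8, 89.8% had the same sign in BCS24, and 84.8% the other way round. Across all 17342 genes the fold changes correlated weakly (r = 0.146, rho = 0.224), and no library is shared between the 2 comparisons, though both come from 1 fit. The 68 genes became 0 without BCS8 control 1, 5 without BCS24 control 3 and 10 without BCS24 control 2, and 337 with DESeq2. They became 1 with rRNA share as a covariate and 40 with the replicate block.

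**Figure D3:**
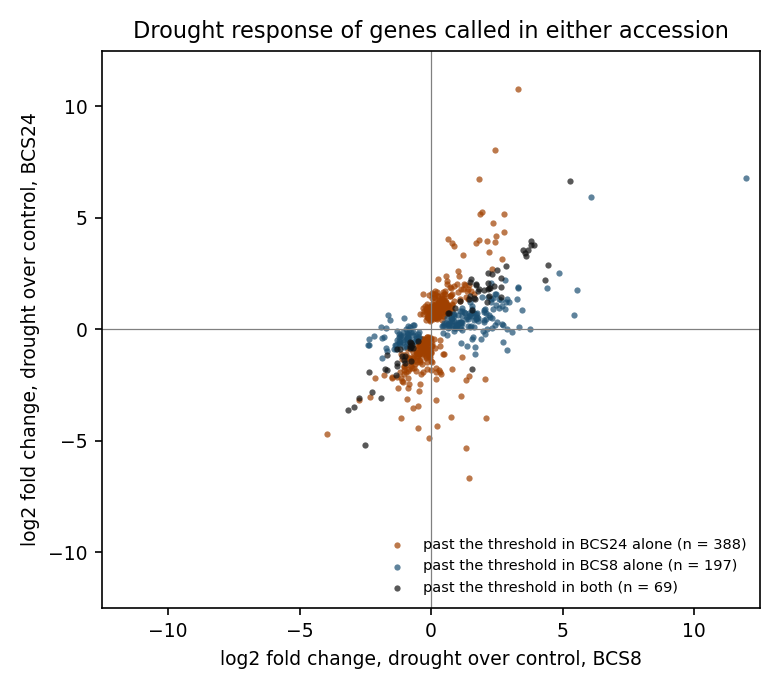
Each point is 1 gene past the threshold in at least 1 accession (654 genes), with the log2 fold change of drought over control in BCS8 on the horizontal axis and in BCS24 on the vertical axis. The 69 genes past the threshold in both accessions lie in the upper right and the lower left, save 1.

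No gene had a drought response that differed between accessions past the threshold: 0 in edgeR, with 2166 at an unadjusted p < 0.05 and a smallest adjusted p of 0.0604. Other tools gave 629 (DESeq2) and 1, 14 and 4 in limma on log2(FPKM + 0.1), log2(FPKM + 1) and quantile-normalized values. The gene closest to the threshold was HORVU7Hr1G037180, annotated by ontology to osmotic stress and ethylene signalling, with 1.91 ± 0.19 in BCS8 and −0.46 in BCS24 (difference −2.37 ± 0.27). EDTS5 HORVU4Hr1G071300 (3.76 in BCS8, 0.01 in BCS24, edgeR adjusted p of the difference = 0.196), HvMS HORVU5Hr1G006780 (0.196) and HORVU5Hr1G008050 (0.225) did not pass either. Nor did DPE2 HORVU2Hr1G021700 (difference 1.28 ± 0.18, adjusted p = 0.107) or glucan phosphorylase HORVU3Hr1G085380 (1.88 ± 0.29, adjusted p = 0.107). Hence a gene past the threshold in 1 accession alone is not shown to respond differently. As lists, the Calvin cycle (median difference 0.61, 7 of 8 positive, camera adjusted p = 0.00393; 0.836 with an estimated correlation) moved further upward in BCS24. So did chlorophyll synthesis (0.35, 20 of 26 positive, adjusted p = 0.0171; 0.836). By description, chlorophyll synthesis and plastid ribosomal proteins (both camera adjusted p = 0.00993; 0.708 with an estimated correlation), sucrose, fructan and starch (0.0278; 0.708), the Calvin cycle and reference genes (both 0.0278; 0.781) did so too. Since the control list of reference genes passed as well, a pass by camera does not by itself show that a list responds differently. By fry 0 lists of either family passed in the interaction. With BCS8 drought 3 and BCS24 control 1 both left out, a choice made because they lie apart in these data, 728 genes passed (274 higher, 454 lower), and 31 with BCS8 drought 3 alone left out. In simulated data 13% and 8% of 2-fold differences were recovered, and 71% and 61% of 4-fold ones.

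Between the accessions in control, Rpg1 HORVU7Hr1G001450, a stem rust resistance gene, was nearly without counts in BCS24 (59.8 ± 4.12 against 0.0431 CPM, −10.39 ± 0.51, edgeR adjusted p = 2.86e-06, n = 3 per group). An MLO-like gene, HORVU7Hr1G002390, stood the other way, at 0.183 in BCS8 and 294 ± 122 in BCS24 (10.61 ± 0.95, edgeR adjusted p = 5.15e-05). Cytokinin oxidase HORVU1Hr1G057860 was higher in BCS24 (3.94 ± 0.33, 16.8 against 258 CPM), as were GER2a HORVU7Hr1G036720 (5.44 ± 0.54), glycosyltransferase HORVU3Hr1G078840 (3.96 ± 0.82) and KSL1 HORVU2Hr1G099480 (3.03 ± 0.34). Higher too were the chlorophyll a-b binding genes HORVU1Hr1G088920 (3.21 ± 0.81), HORVU5Hr1G109250 (3.10 ± 0.67) and HORVU6Hr1G016880 (2.99 ± 0.67). An Fe-S cluster assembly gene, HORVU1Hr1G089730, had 0 counts in all 6 BCS24 libraries and was at least 120-fold lower in control. Arginine decarboxylase HORVU1Hr1G002090 (−6.93 ± 1.93), NRT1/PTR family 7.1 HORVU6Hr1G070450 (−4.50 ± 0.94) and ABC1037 HORVU7Hr1G001600 (−3.46 ± 0.27) were lower. So were allene oxide cyclase HORVU6Hr1G081000 (−2.72 ± 0.83), shikimate kinase-like HORVU1Hr1G050970 (−2.06 ± 0.26) and HVA22-like HORVU5Hr1G016810 (−1.92 ± 0.55). Allene oxide cyclase was not past the threshold in 12 of 18 alternatives, and arginine decarboxylase and HVA22-like each in 9 of 18.

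Ribosomal protein genes were lower in BCS24 control: of 135 genes of the cytosolic large subunit 73 were lower and 2 higher (98 and 2 adjusted over the list alone). Their median was −0.56 (camera adjusted p = 1.37e-13; adjusted p = 0.859 with an estimated correlation). By description 18 of 35 cytosolic ribosomal genes (adjusted p = 8.82e-05; 0.901 with an estimated correlation) and 12 of 30 plastid ones (0.0242; 0.901) were lower. Photosystem genes were higher (14 of 84, with 2 lower, 0.016; 0.901). By Fisher's test 29 ontology terms passed among the higher genes, microtubule motor activity (15 of 43, 4.26 expected, adjusted p = 0.00643) and light harvesting in photosystem I (13 of 34, 3.37 expected) among them. Among the lower ones 26 passed, led by structural constituent of ribosome (136 of 365, 33.22 expected, adjusted p = 3.39e-47) and chloroplast stroma (109 of 458, 41.68 expected). Of 17 wax genes 6 were higher and 1 lower, of 445 defence genes 61 were higher and 24 lower, and of 62 glutathione transferases 10 were higher and 5 lower.

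In all, 3317 genes differed in control (edgeR; 1731 higher and 1586 lower in BCS24), 722 and 644 of them at least 2-fold. The count fell to 1690 and 1788 without BCS8 control 2 or 3, and to 1402 and 1423 without BCS24 control 2 or 3. These are differences in counts, and the aligner and genome build are not given. Sequence of an accession missing from or unlike the reference may add to them, also for the genes named above. No genome sequence was at hand to test this.

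Under drought the same genes led: Rpg1 HORVU7Hr1G001450 (66.2 ± 9.60 against 0.0432 CPM, −10.49 ± 0.51, edgeR adjusted p = 3.16e-06, n = 3 per group), MLO-like HORVU7Hr1G002390 (9.43 ± 0.92), cytokinin oxidase HORVU1Hr1G057860 (5.28 ± 0.35, edgeR adjusted p = 7.55e-06) and GER2a HORVU7Hr1G036720 (5.15 ± 0.53). KSL1 HORVU2Hr1G099480 (3.50 ± 0.35), CASP-like HORVU3Hr1G099690 (3.30 ± 0.54), glycine-tRNA ligase HORVU7Hr1G000550 (2.61 ± 0.19) and 3-ketoacyl-CoA synthase HORVU4Hr1G063420 (2.42 ± 0.52), an enzyme of wax synthesis, were higher too. Fe-S assembly HORVU1Hr1G089730 was at least 173-fold lower. NAR2.3 HORVU6Hr1G053710, of nitrate transport, was lower by 6.73 ± 1.66 (edgeR adjusted p = 0.016), glycosyltransferase HORVU1Hr1G092650 by 6.51 ± 1.69. The dirigent genes HORVU5Hr1G094710, HORVU5Hr1G094700 and HORVU5Hr1G094740 were lower as well (−6.17 ± 1.59, −5.51 ± 1.32 and −5.50 ± 1.23). The large-subunit rRNA locus ENSRNA049485995 was lower by 5.62 ± 1.70, where rRNA share was 1.65% in BCS8 and 0.486% in BCS24. Of the 16 genes the rule named for this comparison, 5 were no longer past the threshold with a replicate block in the 6 drought libraries. The control differences of arginine decarboxylase HORVU1Hr1G002090 (drought adjusted p = 0.0966 in edgeR), HVA22-like HORVU5Hr1G016810 (−0.85, adjusted p = 0.253) and the 3 chlorophyll a-b binding genes (1.94, 1.41 and 1.41 for HORVU1Hr1G088920, HORVU5Hr1G109250 and HORVU6Hr1G016880) did not pass under drought.

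Of the large ribosomal subunit genes 81 of 135 were lower and 2 higher under drought (100 and 2 adjusted over the list alone, median −0.55, camera adjusted p = 1.33e-11; adjusted p = 0.926 with an estimated correlation). By description 19 of 35 were lower (0.000238; 0.773). Defence genes had 63 higher and 74 lower, glutathione transferases 10 and 22, and wax genes 8 and 0. By Fisher's test 36 terms passed among the higher genes, with the kinesin complex (20 of 51, 6.83 expected, adjusted p = 0.000654) among them. Among the lower genes 25 passed, with structural constituent of ribosome (136 of 365, 49.38 expected, adjusted p = 4.7e-28), response to chitin (25 of 55, 7.44 expected, adjusted p = 1.26e-06) and glutathione transferase activity (22 of 62, 8.39 expected, adjusted p = 0.00112). The term rRNA transcription (14 of 14, 1.89 expected) passed too, in libraries where 106 of 235 rRNA genes were at least 2-fold lower in BCS24 and rRNA share was 1.65% in BCS8 and 0.486% in BCS24.

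Under drought 4749 genes differed (edgeR; 2307 higher, 2442 lower), and at least 2-fold 788 were higher and 1413 lower. Higher genes made up 48.6%, 37.6% with limma on log2(FPKM + 0.1) and 64.6% of 5271 after quantile normalization. With only the 6 drought libraries in the fit 1855 genes passed, and 2567 when replicate number was added as a block. With rRNA share as a covariate 1504 passed. Left out singly, BCS24 drought 1 gave 2036, BCS8 drought 2 gave 2567 and BCS24 drought 3 gave 3106. In both conditions 1154 genes were higher (230.27 expected) and 891 lower (223.33 expected), and the fold changes of the 2 conditions, which share no library, correlated at r = 0.814 (rho = 0.632). Sequence of an accession missing from or unlike the reference may add to the differences under drought too. It would be the same in both conditions, so this correlation cannot tell it from a difference in expression.

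Nothing in the labels says that the replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical.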

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

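The tests of neighbouring genes, with and without snoRNA genes, of sequence missing from an accession, of rRNA share in BCS24 control 1 and of organelle genes, the lists by description, and the limits on how far the ratios and the clock value had to clear their bounds were chosen only after the results were seen.

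The drought effect on the make-up of the libraries differed between the 2 accessions for 4 of 5 measures, by a test of the difference between the effects (exact permutation, 400 relabellings, adjusted over 5 measures). Genes with at least 1 FPKM rose by 339 in BCS8 and fell by 469 in BCS24 (difference −807.7, exact p = 0.005, adjusted p = 0.025), with no overlap between control and drought in either. The share of the 10 most counted genes differed by 2.42 percentage points (exact p = 0.01), that of rRNA by −1.74 (exact p = 0.035, adjusted p = 0.0438) and that of mitochondrial genes by −0.0366 (exact p = 0.015). Group means of these 3 shares moved in opposite directions, but control and drought overlapped in at least 1 accession for each, and for rRNA in both. The share of plastid genes did not pass (−0.0548, exact p = 0.1). The rRNA genes were not taken out of the mitochondrial and plastid shares. The mitochondrial share followed the rRNA share, from 0.0059% beside 0.202% in BCS24 drought 1 to 0.0468% beside 2.07% in BCS24 control 2. It is thus not a measure separate from rRNA share, and does not show a change of other mitochondrial genes.

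The lists whose drought effect differed between the accessions by camera were the Calvin cycle (adjusted p = 0.00393) and chlorophyll synthesis (0.0171) by ontology, and, by description, chlorophyll synthesis (0.00993), plastid ribosomal proteins (0.00993), sucrose, fructan and starch (0.0278), the Calvin cycle (0.0278) and reference genes (0.0278). None passed with an estimated correlation or by fry, and other splits of the treatment labels gave as many lists by ontology. One gene was called in opposite directions: HORVU3Hr1G056640, without description or ontology term, rose in BCS8 (1.57 ± 0.28) and fell in BCS24 (−1.78 ± 0.30), and its difference of −3.36 ± 0.41 had an edgeR adjusted p of 0.0676.

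BCS24 had 644 genes at least 2-fold lower than BCS8 in control and 1413 under drought. A gap of this size (769) was reached by 10 of 100 splits of the treatment labels, the real one included, with a highest of 1094, so chance cannot be excluded. Carry-over of rRNA and other RNA without a poly(A) tail may add to it, since rRNA genes went from 0 to 106 of 235, but among protein-coding genes the ratio was still 2.05 (597 to 1222), and 1.3 to 3.1 with each library left out, a spread that keeps this open. A larger spread between the control libraries cannot be told apart either: counted by fitted fold change alone the ratio was 1.61 (1270 to 2050), over the bound of 1.5 set before, but 1.44 to 1.82 with each library left out. The 28 organelle genes other than rRNA had a median of −0.09 under drought, with 16 negative, which decides nothing about the rRNA genes, and a biological cause in the accessions was not tested.

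Genes with at most 3 counts in every library of 1 accession and at least 1 FPKM in every library of the other numbered 28 for BCS8 and 57 for BCS24. They formed 7 neighbouring pairs along the chromosomes, against a mean of 0.22 and a highest of 6 in 10000 permutations (permutation p = 1e-04, the smallest they can give), which argues against chance placement. Of the 7 pairs, 3 hold snoRNA genes within 2 kb, which can share 1 transcript; among protein-coding genes alone 4 pairs remained, against a mean of 0.19 and a highest of 3 in permutations of those genes (permutation p = 1e-04). The pairs (value 7) occur in both directions, as sequence of one accession missing from or unlike the reference would give. No genome sequence was at hand to tell it from silent neighbouring genes or from like neighbours that share reads. The permutations take neighbouring genes as independent. Neighbouring means next in order among the tested genes, so untested genes can lie between. The protein-coding pairs spanned 64.7, 127.2, 153.9 and 2.9 kb. One protein-coding block on 7H held genes from 3536671 to 3690570, and another on 2H from 18203684 to 18268415, as the deposited table gives them, build not given.

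BCS24 control 1 lay nearer the BCS24 drought libraries than the other controls did. A drought library with the wrong label is not excluded. On the 266 genes called in BCS8, BCS24 control 1 lay at 0.03 on a scale from the other BCS24 controls (0) to BCS24 drought (1). On all genes it lay at 0.57. The 266 genes came from a fit that counted this library as a control when it estimated the spread. Genes on which it was like drought were thus less likely to be called, so the 0.03 cannot decide the question. rRNA carry-over or RNA quality stays open, as deviations of rRNA share and of component 2 over 12 libraries gave r = 0.483, rho = 0.315, exact permutation p = 0.128, and r = 0.416 without the 2 farthest. Another time of day at harvest cannot be told apart: the 15 clock genes deviated by a median of 0.15, at percentile 35.5 of random sets (0.1 to 0.3 from the 5th to the 95th), under the bound of 50 set before but within that spread. A biological cause in the plants of this library was not tested.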

How the results depend on the processing

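DESeq2, the rRNA covariate, removal of rRNA and organelle genes, removal of BCS8 drought 3 with BCS24 control 1, lists by description and the 6-library block were chosen only after the results were seen. Limma on log2(FPKM + 1) was planned as the main test and became an alternative once the files were seen. Unless its construction shows it, the cause of a change was not tested. Of 2300 values of named genes under alternatives, 1714 kept direction and side of the threshold, 553 were no longer past it, 19 were newly past it, 14 near 0 changed sign and 0 called ones reversed. Median-of-ratios scaling (266 and 452 drought calls), transcript sums and removal of rRNA and organelle genes (275 and 438) kept every count of genes within 1.5 times. Of the 3, only median-of-ratios scaling was run on the gene lists, with the same numbers of lists past the threshold (2, 8 and 2). Ontology terms were run under none of the 3. Transcript sums held nearly the same counts as the gene table (49745046 against 49745073 in BCS8 control 1). They are thus no separate check, and all their 127 named values count among the 1714.

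Drought calls in BCS8 (266) were 438 with limma on log2(FPKM + 1), 447 with quantile normalization, 151 without filter, 156 with the replicate block, 29 with the rRNA covariate, 1182 with DESeq2 and 2 with only 6 libraries; each library left out gave 0 to 320. Drought calls in BCS24 (460) were 751 and 766 with limma on log2(FPKM + 0.1) and log2(FPKM + 1), 241 without filter, 305 with the replicate block, 270 with a 2-fold minimum, 15 with the rRNA covariate, 985 without BCS8 drought 3 and BCS24 control 1, and 1803 with DESeq2; leaving out gave 19 to 408. Interaction calls (0) were 1, 14 and 4 in limma on log2(FPKM + 0.1), log2(FPKM + 1) and quantile-normalized values, 728 without the 2 libraries and 629 with DESeq2; leaving out gave 0 to 31 (4 without BCS8 control 3, 1 without BCS8 drought 1 or 2).

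Accession calls in control (3317) were 1366 with a 2-fold minimum and 2137 with the rRNA covariate, and 1402 to 2873 with a library left out. Those in drought (4749) were 2201 and 1504, 1855 with only 6 libraries and 2567 with the replicate block of 6 drought libraries, and 2036 to 5192 with a library left out. The mean drought effect (1191) gave 438 with a 2-fold minimum, 2334 with DESeq2, 1299 with the rRNA covariate and 514 to 1186 with a library left out (529 without BCS8 control 1; 549, 514 and 746 without BCS24 control 2, control 3 and drought 1). Genes shared by the accessions (68) were 31 without filter, 40 with the replicate block, 1 with the rRNA covariate and 337 with DESeq2, and 0 to 75 with a library left out (13 and 24 without BCS8 control 3 and drought 1; 34, 11 and 20 without BCS24 control 1, drought 1 and drought 2).

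The replicate block over 12 libraries changed no other count by over 1.5 times (interaction 0, accession in control 3010). The numbers of BCS8 control and drought did not deviate together (0.241, −0.376 and −0.407), nor did those of BCS24 (0.123, 0.224 and −0.09) or of the controls (−0.145, −0.008 and 0.216).

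Lists past the threshold in BCS8 (2) were 1 without filter, 0 with an estimated correlation and 5 by description, and 2 to 3 with a library left out. In BCS24 (8) they were 5 with limma on log2(FPKM + 1), 5 without filter and 0 with an estimated correlation, and 6 to 9 with a library left out. In the interaction (2) they were 0 with an estimated correlation, 5 by description and 4 without the 2 libraries, and 0 to 5 with a library left out (1 without BCS8 control 1, 0 without BCS24 drought 3). Ontology terms in drought (24) were 9 with a 2-fold minimum and 38 without the 2 libraries. DESeq2 gave no adjusted p for 32 genes.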

Other observations

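The mean drought effect over the accessions, and its splits of samples, were chosen only after the results were seen.

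Averaged over both accessions, drought raised cold-acclimation genes and 3 jasmonate ZIM-domain genes beside those of ABA. The CRT/DRE binding factor 1 gene HORVU0Hr1G016540 rose by 5.24 ± 0.52 (edgeR adjusted p = 0.00141), on 0.687 and 3.66 CPM in BCS8 and 0.006 and 2.23 in BCS24. Its 0.006 in BCS24 control lies under 3 counts per library (0.0545 CPM in that group), so the size of the rise is uncertain. CBF14 HORVU5Hr1G080350 rose by 1.17 ± 0.30 (edgeR adjusted p = 0.0421), and cold acclimation held 8 of 31 risen genes (1.27 expected, Fisher adjusted p = 0.00309). The jasmonate ZIM-domain genes HORVU4Hr1G076820 (1.68 ± 0.42), HORVU4Hr1G076840 (1.17 ± 0.23) and HORVU2Hr1G031310 (1.14 ± 0.26) rose, within a term of jasmonate regulation with 5 of 12 genes (adjusted p = 0.00769). The 8 genes of jasmonic acid metabolism did not pass (camera adjusted p = 0.922), with a median of −0.12 in edgeR, 0.13 with limma on log2(FPKM + 1) and 0.15 after quantile normalization. The 13 jasmonate genes by description rose (median 0.79, camera adjusted p = 0.00337; 0.43 with an estimated correlation). Of 199 genes of water deprivation 28 rose and 8 fell (camera adjusted p = 0.00945; adjusted p = 0.411 with an estimated correlation), and the ABA biosynthesis list rose (2.73e-07; 0.231). ABA receptors HORVU1Hr1G050110 and HORVU2Hr1G014670 fell by 0.82 ± 0.13 and 0.91 ± 0.18.

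Autophagy genes fell by small amounts in the same mean: ATG5 HORVU2Hr1G049500 by 0.46 ± 0.11, ATG11 HORVU6Hr1G029550 by 0.40 ± 0.09, ATG3 HORVU1Hr1G056110 by 0.25 ± 0.06 and ATG18a HORVU3Hr1G098020 by 0.22 ± 0.05, with 6 of 20 genes of autophagosome assembly lower (0.58 expected, Fisher adjusted p = 0.0197). The lists of chlorophyll synthesis (camera adjusted p = 0.00407; 0.536 with an estimated correlation) and of the large ribosomal subunit (0.00146; 0.66) rose, and nitrate assimilation fell (0.0285; 0.443). In all 1191 genes passed in edgeR (693 higher, 498 lower; 3991 with an unadjusted p < 0.05), 645 of which passed in neither accession alone. Higher genes made up 58.2%, 33.8% with limma on log2(FPKM + 0.1), 33.1% on log2(FPKM + 1) and 43.9% after quantile normalization.

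Other splits of the samples were tried for each count. For drought in BCS8 (266), drought in BCS24 (460), accession in control (3317) and accession in drought (4749) the highest other split gave 1 gene each, the real one being 1 of 10, which are too few for a share under 0.05. Over 100 splits of the treatment labels within accessions, chance is argued against where the real split alone was as large (1 of 100, the smallest share possible). This held for the genes shared by the accessions (68, highest other 0), the mean drought effect (1191, highest other 130) and the ontology terms in drought (24, highest other 5). It also held for the ABA biosynthesis list in the mean effect (−log10 p of 7.96, highest other 6.21, by camera at the preset correlation). That list has a camera adjusted p = 0.231 with an estimated correlation, and some of its genes may share reads. The 68 shared genes are no test of sharing as such. In the other splits at most 5 genes were called in BCS8, so few could be shared. For the terms, the split that exchanges all labels in BCS24 alone was not drawn. It makes the same calls with the BCS24 directions turned round, so it would give 24 terms again. Chance cannot be excluded for the lists in the interaction (2, highest other 9, with 79 of 100 as large). For the interaction calls the splits test nothing, since no split can lie below the real count of 0 (100 of 100 as large; highest other 213). The split with 213 kept the BCS24 groups whole and mixed those of BCS8. For lists in BCS8 (2; 5) all 10 of 10 splits and in BCS24 (8; 10) 3 of 10 were as large.

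Sterol genes HORVU4Hr1G018180 and HORVU4Hr1G018150 rose in BCS24 by 3.86 ± 0.43 and 3.72 ± 0.44, and 3 pyruvate kinase genes rose there, HORVU1Hr1G054380 most (1.24).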
